A study of Mus musculus with 9 samples.

How the data were processed

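The data are RNA-seq libraries of CH12F3 mouse B-lymphoma cells with a Ligase4 knockout, stimulated for 24 h and treated with DMSO, tazemetostat or valemetostat. Each of the 3 groups has 3 libraries. Per the labels' protocols, poly(A) RNA was selected, fragmented, copied with random hexamers and sequenced as 150-nt read pairs. The authors deposited a table of whole-number counts per gene and library. They also deposited a table of log2 values. Raising 2 to these values and subtracting 1 gives TPM (transcript abundances scaled to a fixed total) in whole hundredths in 100% of values at a tolerance of 1e-06. The deposited log2 values are therefore log2(TPM + 1), with TPM rounded by the authors. The genome build is mm9, per the submitters' processing notes. The aligner, the counting program, its use of strand and the annotation are not given in the sources used here. Between 15 and 48 genes per library have 0 counts and a TPM above 0, so the deposited counts may be rounded estimates.

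The count table has 45361 gene identifiers, of which 26263 are at 0 in all libraries. The table has 0 rows named as mitochondrially encoded (mt-), so such genes were not analysed here. The 1329 identifiers with no symbol carry 0.00086 to 0.00131% of a library's counts. They were kept under their identifiers. The reference used here was GENCODE M21, which lists 42117 of the identifiers and is on another build. It served only for transcript lengths, GC content and the order of genes along chromosomes, and no coordinates are given. Library totals run from 34080504 to 46675110 counts, so 3 counts correspond to 0.0643 to 0.088 CPM (counts scaled to a common library total). Intervals on counts and floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Reads from near-identical copies, overlapping genes and antisense partners could not be told apart in these counts. Values of MHC, immunoglobulin, Gbp, Oas and haemoglobin genes are therefore uncertain.

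Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, using TMM scaling and the robust quasi-likelihood F test. All 9 libraries entered 1 fit with 3 groups, which shares an estimate of the spread. The filterByExpr filter by group, with a minimum count of 10 and a minimum total of 15, kept 12580 genes, which hold at least 99.97% of each library's counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. A 2-fold call also needed an absolute log2 fold change of at least 1. Errors of log2 fold changes are the absolute log2 fold change over the square root of F, used as standard errors, and intervals are 95%. For large folds from a level near 0 counts they understate the counting error. CPM are given as mean ± SD of 3 libraries with TMM scaling. The comparisons were tazemetostat against DMSO, valemetostat against DMSO, valemetostat against tazemetostat, and the mean of both inhibitors against DMSO. The labels do not say that replicates came from separate cultures. The p-values then measure the spread between these libraries, which may be technical. No pair of replicates agreed within sampling noise, with chi-square per degree of freedom from 5.21 to 12.95.

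The groups, tests, 37 gene lists, named genes and most alternatives were fixed before the data were examined. Gene lists with at least 3 measured members, 36 in all, were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Their p-values were Benjamini-Hochberg adjusted over the 36 lists. Each list test was repeated with an estimated correlation and with fry. A list member counts as risen or fallen if it was called among all tested genes, and the count adjusted over the list alone is also given. The named genes are 14 chosen in advance and, per pairwise comparison, up to 10 called genes in each direction with the largest fold change. The latter needed a mean of at least 1 log2 CPM, no overlap between the groups and a symbol of a studied gene. Up to 4 called members with the smallest p are also named per list. Members named because they moved against the rest of their list (Stat2, Nlrc5, Ciita and Sfr1) were chosen after their values were seen. Some genes named by these rules are not reported here. Folds against a group with 1 to 3 counts are ratios of summed counts with an exact counting interval. Folds against 0 counts are lower bounds against a floor of 3 counts over the group.

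The alternatives were DESeq2 1.42.0, median-ratio size factors, library totals without TMM, no filter on counts, a filter of at least 1 CPM in 3 libraries, and limma-trend on the deposited log2(TPM + 1) values. Others were the replicate number as a term, a fit of the compared groups alone, and leaving out each library in turn. A transcript length and GC offset, a spline with 5 degrees of freedom per library over genes of at least 3 log2 CPM, was added after seeing the data. Leaving out libraries in the list tests was also added then, as was a linear fit of the mean of the chromatin factor list per library on group and on the library's Spearman's rho with transcript length. The concordance of the inhibitors was set beside 20 simulations of groups drawn around the observed DMSO means. These leave out the error of the shared DMSO libraries. The gene test was tested on simulated data with the means and library sizes of tazemetostat against DMSO and 12382 genes. It recovered 74.6% of 1.5-fold, 85.1% of 2-fold and 93.9% of 4-fold changes and called 8 of 12187 unchanged genes. With the length trends of the real libraries in the simulation, it called 187 of 12206 unchanged genes, and 5 with the offset. The list test was run only without length trends and with genes drawn independently. It called the changed list of 29 genes and 0 of 30 random lists. This says nothing on lists of correlated genes or on lists under a length trend.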

Results

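RNA was sequenced from CH12F3 cells, a mouse B-lymphoma line that can switch its immunoglobulin class from IgM to IgA in culture. The cells lacked Ligase4, which seals DNA breaks in classical end joining, and had been stimulated with anti-CD40, IL-4 and TGF-β for 24 h. There were 3 libraries with DMSO, 3 with tazemetostat, an inhibitor of the H3K27 methyltransferase EZH2, and 3 with valemetostat, an inhibitor of EZH1 and EZH2. The stated question was how transcription changes after either inhibitor. Total counts per library ran from 34080504 to 46675110. The first principal component held 57.8% of the variance and separated the DMSO libraries from the 6 inhibitor libraries. Across genes, correlations of log2 CPM were 0.988 to 0.991 within a group, 0.987 to 0.989 between the inhibitors and 0.965 to 0.969 between inhibitor and DMSO libraries.

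The targeted gene, Lig4, had 30, 39 and 29 counts in the DMSO libraries, 59, 21 and 49 with tazemetostat and 46, 31 and 33 with valemetostat. Which part of it was deleted is not given in the sources used here, so these counts check nothing. Its level was 0.859 ± 0.252 CPM in DMSO, 1.05 ± 0.488 CPM with tazemetostat and 0.989 ± 0.16 CPM with valemetostat (SD, n = 3 each).

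Tazemetostat raised genes that were nearly silent in DMSO cells. Hdac9, a class IIa histone deacetylase, was at 0.0541 ± 0.0504 CPM in DMSO and 19.4 ± 1.88 CPM with tazemetostat (SD, n = 3 each), a log2 change of 8.48 ± 0.24. That DMSO level lies under 3 counts per library, so the error of 0.24 understates its counting error. Mctp1, a calcium-binding membrane protein, rose by 7.60 ± 0.18 on the log2 scale and Nab1, a co-repressor of EGR factors, by 5.34 ± 0.18. Igf1, a growth factor, had 2 counts in the 3 DMSO libraries and rose 338-fold (counting interval 93.1 to 2790). The milk protein gene Csn3 had 3 counts there and rose 221-fold (75.3 to 1070). Dnah12, Map2, Fam107a, Sh3tc2 and Fcer1a rose by 5.85 to 6.43 on the log2 scale. The falls were smaller. Lilrb4a, an inhibitory receptor with a close paralog, was at 8.62 ± 2.26 CPM in DMSO and 2.53 ± 0.0654 CPM with tazemetostat, a log2 change of -1.77 ± 0.19. Chd5, a chromatin remodeller, changed by -1.44 ± 0.21, Gnaz, a G protein subunit, by -1.28 ± 0.10 and Tsc22d2 by -1.02 ± 0.06 on the log2 scale. Col11a2, Uevld, Adtrp, Lrrc45, Sfxn4 and Nebl changed by -1.37 to -1.02. The largest edgeR quasi-likelihood adjusted p of these 20 genes was 0.00207, for Sfxn4.

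Of 12580 genes tested, 4794 (38.1%) were called with tazemetostat, 2508 higher and 2286 lower. With library totals in place of TMM the majority turned, with 2237 higher and 2646 lower. Most calls were small, and 83.2% lay under 2-fold. Among the 806 genes changed at least 2-fold, 696 were higher (86.4%), and 476 of these were under 1 CPM in DMSO. The 3 tazemetostat and 3 DMSO libraries did not overlap for 5963 genes (47.4%, against 10% by chance). With the deposited log2(TPM + 1) values 3100 genes were called, 38.0% of them higher against 52.3% in the counts, and 207 at least 2-fold. Chd5, Uevld and Nebl were not called there, with limma-trend adjusted p = 0.263, 0.0907 and 0.114, and a filter of at least 1 CPM left 531 genes at 2-fold.

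Interferon-stimulated genes rose together with tazemetostat. Of 38 measured members 28 rose, 15 of them at least 2-fold, and 1 fell (Stat2), with 31 called when adjusted over the list alone. Camera gave adjusted p = 3.19e-11, and adjusted p = 0.0113 with an estimated correlation, the only list call against DMSO that held with it. Gbp2, an interferon-induced GTPase, went from 2.40 ± 0.144 to 11.6 ± 0.234 CPM (SD, n = 3 each), and Gbp3 rose by 1.68 ± 0.08 on the log2 scale. Lgals3bp, a secreted glycoprotein, rose by 1.10 ± 0.05. In MHC class I presentation 17 of 22 members rose and 1 fell (19 called when adjusted over the list alone), with camera adjusted p = 3.31e-07 and adjusted p = 0.165 with an estimated correlation. H2-D1, a class I heavy chain, rose by 0.46 ± 0.04, B2m, the class I light chain, by 0.45 ± 0.05 and Tapbp and Psmb8 by 0.45 ± 0.04 and 0.41 ± 0.05. The member that fell was Nlrc5, a transactivator of class I genes, at -0.46 ± 0.09. In MHC class II presentation 10 of 14 members rose, led by the lysosomal reductase Ifi30 (0.60 ± 0.04) and the peptide-loading genes H2-DMa and H2-DMb2 (0.51 ± 0.05 and 0.43 ± 0.04). The class II transactivator Ciita fell by 0.21 ± 0.05. The list had 12 members called when adjusted over the list alone, camera adjusted p = 0.000151, and adjusted p = 0.297 with an estimated correlation.

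Further lists were higher with tazemetostat. Among IL-4 and STAT6 targets 10 of 19 rose and 3 fell (13 called when adjusted over the list alone). Fcer2a, the low-affinity IgE receptor, rose by 1.35 ± 0.06 and the cytokine signalling inhibitor Cish by 1.08 ± 0.08, while the repressor Bhlhe41 fell by 0.64 ± 0.06. The camera adjusted p of the list was 0.00176, and adjusted p = 0.297 with an estimated correlation. In glycolysis 11 of 19 rose (11 when adjusted over the list alone), among them the kinases Pfkm (0.54 ± 0.06) and Hk1 (0.28 ± 0.05). Its camera adjusted p was 0.000653, and adjusted p = 0.275 with an estimated correlation. Of 21 measured T cell and NK cell genes 9 rose (9 when adjusted over the list alone). Ctla4, an inhibitory receptor, rose by 1.11 ± 0.08, the transcription factors Lef1 and Tcf7 by 0.85 ± 0.07 and 0.78 ± 0.07 and Il7r, a cytokine receptor, by 1.30 ± 0.18. The list had camera adjusted p = 0.00176, and adjusted p = 0.135 with an estimated correlation.

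Some genes of chromatin activation and DNA repair fell with tazemetostat. Of 21 H3K27 demethylases and activating chromatin factors 14 fell and 0 rose (15 called when adjusted over the list alone). Kmt2a, a histone H3K4 methyltransferase, went from 106 ± 9.41 to 59.9 ± 5.98 CPM (SD, n = 3 each), and Setd2, Arid1a and Nsd2 changed by -0.46 ± 0.06, -0.34 ± 0.05 and -0.32 ± 0.05 on the log2 scale. The list had camera adjusted p = 4.61e-06, and adjusted p = 0.366 with an estimated correlation. In homologous recombination 9 of 26 fell and 1 rose, Sfr1 (10 when adjusted over the list alone), with Brca2 at -0.55 ± 0.06 and Brca1 at -0.39 ± 0.05. For this list camera adjusted p was 0.0052, and adjusted p = 0.297 with an estimated correlation. In alternative end joining 4 of 12 fell (4 when adjusted over the list alone). Polq, the polymerase of theta-mediated joining, changed by -0.77 ± 0.08 and Parp1 by -0.15 ± 0.04. This list had camera adjusted p = 0.0143, and adjusted p = 0.198 with an estimated correlation. In DNA damage checkpoint signalling 10 of 17 fell (10 when adjusted over the list alone), with the kinase Atm at -0.41 ± 0.07 and Timeless at -0.30 ± 0.05. Here camera adjusted p was 0.0189, and adjusted p = 0.359 with an estimated correlation. In class switch machinery 15 of 33 fell and 5 rose (21 when adjusted over the list alone). The risen members included the transcription factor Batf (0.49 ± 0.05) and the fallen ones Trp53bp1 (-0.37 ± 0.06) and Supt6 (-0.28 ± 0.05). Camera gave adjusted p = 0.0353, adjusted p = 0.275 with an estimated correlation, 0.0627 on log2(TPM + 1) values and 0.0572 with the filter of at least 1 CPM. The single-gene calls of Brca2 and Nsd2 were also lost on log2(TPM + 1) values (limma-trend adjusted p = 0.155 and 0.0579).

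Small fold changes against DMSO also moved with transcript length, as the plot by transcript length shows. Over genes of at least 3 log2 CPM changed under 2-fold, Spearman's rho across genes, which are not independent replicates, was -0.36 with tazemetostat, -0.43 with valemetostat and -0.22 between the compounds. Libraries also differed within a group, with rho of the deviation from the mean of all libraries at 0.29, 0.49 and 0.21 in DMSO 1, 2 and 3, at -0.03, -0.01 and -0.45 in tazemetostat 1, 2 and 3, and at -0.26, -0.46 and -0.24 in valemetostat 1, 2 and 3. The mean deviation of the chromatin factor genes, in the same order of libraries, lay at 0.20, 0.27 and 0.12, at -0.03, -0.01 and -0.18, and at -0.11, -0.19 and -0.09 on the log2 scale. Without tazemetostat 3, 4047 genes were called with tazemetostat, and without DMSO 2, 3926 with tazemetostat and 4072 with valemetostat. The median transcript was 8187 nt in the chromatin factor list, 1447 nt in MHC class II presentation, 1777 nt in MHC class I presentation and 2990 nt over all tested genes. With a length and GC offset, added after seeing the data, the chromatin factor median went from -0.26 to -0.07 with tazemetostat (camera adjusted p = 0.00367) and from -0.33 to -0.14 with valemetostat (adjusted p = 6e-04). Without the offset this list had adjusted p = 0.366 and 0.287 with an estimated correlation. The MHC class II median went from 0.27 to 0.18 and from 0.34 to 0.21. With valemetostat the glycolysis median went from 0.12 to 0.06 and the checkpoint median from -0.13 to -0.08.

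**Figure D1:**
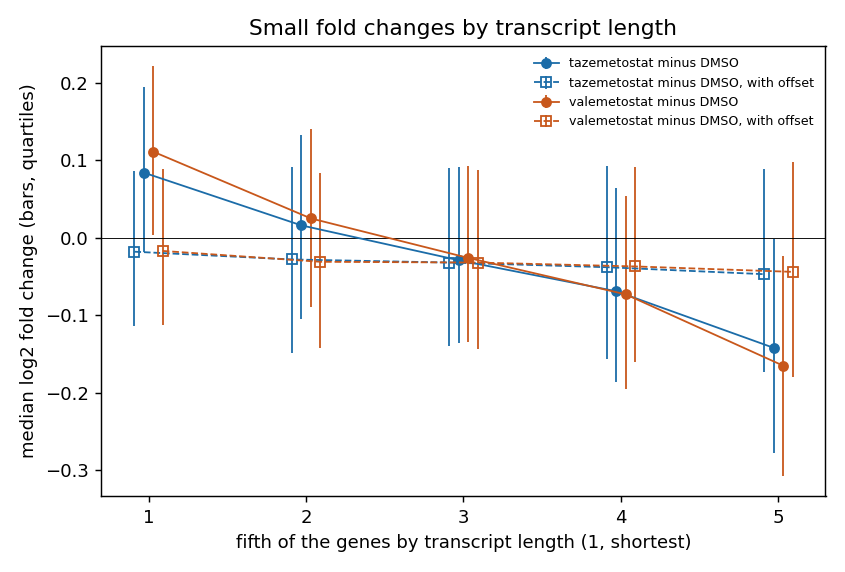
Median log2 fold change (y axis) of tested genes of at least 3 log2 CPM changed under 2-fold, in 5 equal groups by transcript length (x axis, 1 the shortest), with quartiles as bars, for tazemetostat (blue) and valemetostat (orange) against DMSO. Filled points, without offset, fall from 0.08 to -0.14 with tazemetostat and from 0.11 to -0.17 with valemetostat, and open squares, with the length and GC offset, lie between -0.05 and -0.02.

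Among the genes chosen in advance, Ighm, the IgM heavy chain, rose by 0.21 ± 0.05 with tazemetostat and 0.28 ± 0.05 with valemetostat on the log2 scale, with edgeR adjusted p = 0.000915 and 4.29e-05. With tazemetostat that call was lost on log2(TPM + 1) values (limma-trend adjusted p = 0.095). Igha, the IgA heavy chain, was at 128, 129 and 124 CPM, with log2 differences of 0.01 ± 0.05 and -0.04 ± 0.05 that did not pass the test (edgeR adjusted p = 0.856 and 0.512). On log2(TPM + 1) values Igha was called with valemetostat, at -0.15 (limma-trend adjusted p = 0.0344). Myc fell by 0.28 ± 0.04 and by 0.20 ± 0.04. The targets of the inhibitors, Ezh2 and Ezh1, did not pass the test, with Ezh2 at 174 ± 3.79, 178 ± 5.69 and 166 ± 3.71 CPM in the 3 groups. With the length and GC offset Ezh2 was called lower with valemetostat, at -0.11 (edgeR adjusted p = 0.0196). Suz12, another subunit of the complex, changed by -0.18 ± 0.05 and -0.16 ± 0.05, and Eed by 0.04 ± 0.05 and 0.10 ± 0.05, which did not pass. The Suz12 call with valemetostat was lost without DMSO 2 (adjusted p = 0.0683) or valemetostat 2 (adjusted p = 0.0527). Cdkn1a, a cell cycle inhibitor, rose by 0.58 ± 0.17 with tazemetostat and was at 0.29 ± 0.17 with valemetostat, which did not pass. Prdm1, the plasma cell regulator, was at -0.29 ± 0.13 and -0.15 ± 0.13, which did not pass. Cdkn2a and Bcl6 had 0 counts in all 9 libraries and Cdkn1c 1 count, in DMSO.

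**Figure D2:**
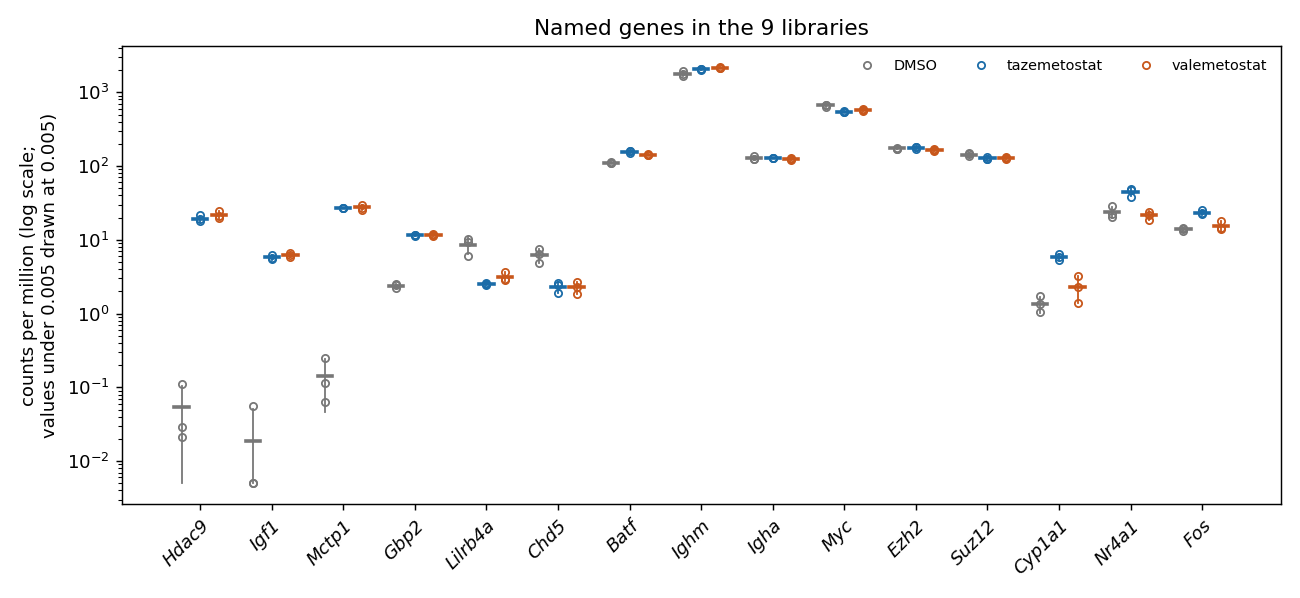
CPM on a log scale (y axis) of 15 named genes (x axis) in the 9 libraries. Circles are libraries, thick bars means and thin lines SD, with values under 0.005 drawn at 0.005. Hdac9 lies at 0.0541 CPM in DMSO and at 19.4 and 21.9 CPM with tazemetostat and valemetostat, and Igha at 128, 129 and 124 CPM.

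Other lists did not pass camera with either inhibitor. Of 12 PRC2 subunits 4 fell with each, Lcor, Mtf2, Phf19 and Suz12 (4 and 4 when adjusted over the list alone), with camera adjusted p = 0.309 with tazemetostat and 0.142 with valemetostat. With tazemetostat the calls of Lcor and Phf19 were lost on log2(TPM + 1) values (limma-trend adjusted p = 0.0606 and 0.0586) and that of Phf19 without tazemetostat 1 (edgeR adjusted p = 0.0836). Of 20 PRC1 subunits 6 rose and 5 fell with each (11 and 12 when adjusted over the list alone, adjusted p = 0.847 and 0.98). Pcgf5 rose by 1.75 ± 0.11 and 1.78 ± 0.11 and Bmi1 by 0.71 ± 0.06 and 0.73 ± 0.06. Of 16 measured HOX genes 5 rose and 2 fell with tazemetostat and 4 rose and 1 fell with valemetostat (7 and 5 when adjusted over the list alone, adjusted p = 0.243 and 0.492). Of 11 developmental regulators 4 rose and 2 fell with tazemetostat and 4 rose and 1 fell with valemetostat (6 and 6 over the list alone, 0.268 and 0.36). Of 4 cyclin-dependent kinase inhibitors 2 and 1 rose (2 and 1 over the list alone, 0.44 and 0.348), and of 6 imprinted genes 3 rose and 2 fell with each (5 and 5 over the list alone, 0.715 and 0.961).

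B cell lists did not pass either. Among 36 mature and germinal centre B cell genes 16 rose and 6 fell with tazemetostat, and 15 rose and 7 fell with valemetostat (23 with each when adjusted over the list alone, camera adjusted p = 0.125 and 0.0778, and for the latter 0.0466 without DMSO 2 and adjusted p = 0.468 with an estimated correlation). Bach2, a B cell repressor, rose by 1.46 ± 0.07 and 1.19 ± 0.07 and Irf8 fell by 0.79 ± 0.06 and by 0.85 ± 0.06. Of 10 immunoglobulin constant region genes 3 rose and 1 fell with each (4 and 4 over the list alone, 0.281 and 0.158, and for the latter 0.044 without DMSO 3 and adjusted p = 0.605 with an estimated correlation), with Ighg2b up by 1.46 ± 0.20 and 1.25 ± 0.20. Of 21 plasma cell genes 4 rose and 5 fell with tazemetostat and 5 rose and 4 fell with valemetostat (9 and 10 over the list alone, 0.745 and 0.951). Of 8 early B cell genes 3 rose and 2 fell, and 3 rose and 1 fell (5 and 4 over the list alone, 0.655 and 0.522).

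In the remaining lists, values with tazemetostat come before those with valemetostat, and counts over the list alone before camera adjusted p. In classical end joining 1 and 2 of 11 fell (1 and 2, 0.679 and 0.743), with Prkdc, the DNA-dependent protein kinase, down by 0.54 ± 0.06 and by 0.76 ± 0.07. Of 34 p53 targets 9 rose and 9 fell, and 7 rose and 4 fell (19 and 11, 0.847 and 0.98). Of 22 apoptosis regulators 7 rose and 4 fell, and 5 rose and 2 fell (13 and 7, 0.847 and 0.98). Of 40 proliferation genes 9 rose and 12 fell, and 9 rose and 11 fell (23 and 22, 0.745 and 0.492). Of 17 off-target and translocation partner loci 7 rose and 4 fell, and 5 rose and 4 fell (11 and 10, 0.715 and 0.98). In the unfolded protein response 4 of 23 rose and 9 fell, and 7 rose and 10 fell (14 and 18, 0.268 and 0.492).

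Among marker lists of other cell types, of 17 measured myeloid genes 9 rose and 4 fell with tazemetostat and 9 rose and 3 fell with valemetostat (13 and 12 when adjusted over the list alone), with camera adjusted p = 0.113 and 0.0778. Of 8 erythroid and megakaryocyte genes 3 rose and 2 fell, and 2 rose and 1 fell (6 and 3 over the list alone, 0.655 and 0.951). Of 6 stromal, endothelial and epithelial genes 2 rose with each and 0 fell (2 and 2 over the list alone), with camera adjusted p = 0.0503 and 0.0637. These were Vim, an intermediate filament gene, which rose by 4.71 ± 0.12 and 4.86 ± 0.12, and the proteoglycan gene Lum, at 0 counts in DMSO and at least 19.2-fold and 21.3-fold higher. The stromal list had adjusted p = 0.416 and 0.42 with an estimated correlation. At the preset correlation it passed with the length and GC offset, at adjusted p = 0.0337 and 0.0374. It also passed with tazemetostat without DMSO 2 (0.0349), tazemetostat 2 (0.0466) or tazemetostat 3 (0.0252), and with valemetostat without DMSO 2 (0.0433) or valemetostat 2 (0.043). Of 25 germline genes 2 were measured, too few to test, and Piwil2 among them fell by 0.70 ± 0.27 with valemetostat. That call was lost without DMSO 1 (edgeR adjusted p = 0.0513), DMSO 2 (0.214), valemetostat 1 (0.173) or valemetostat 3 (0.0603), and with DESeq2 (0.0532), the length and GC offset (0.0527) or log2(TPM + 1) values (0.0885). Median, mean and test differed in sign for 5 lists with tazemetostat, 8 with valemetostat and 7 between the compounds, 0 of them called.

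**Figure D3:**
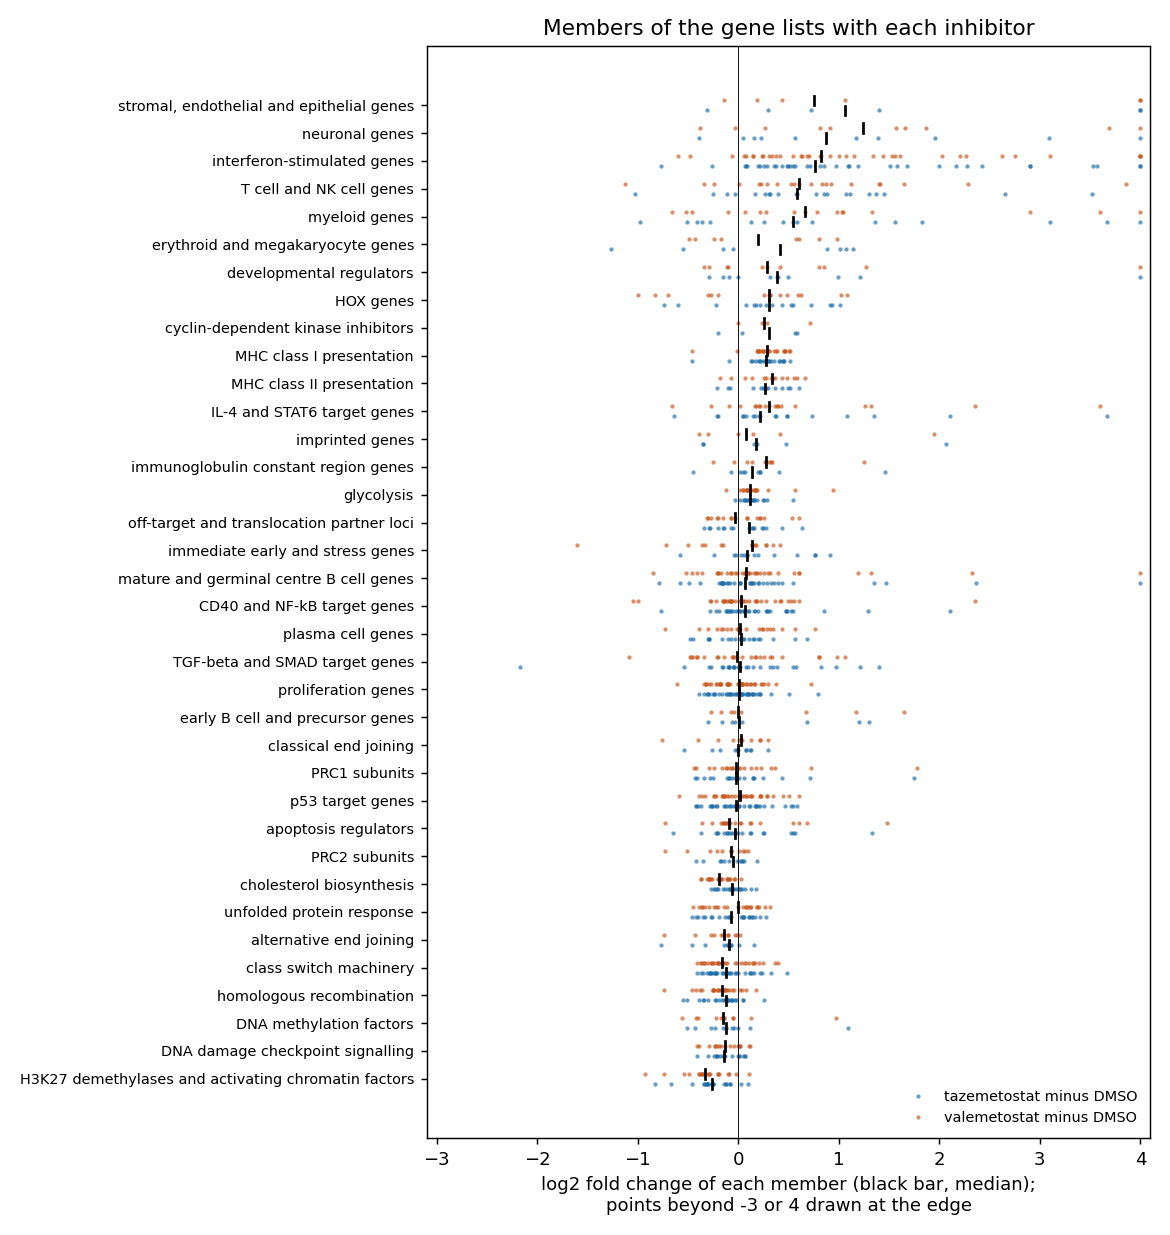
Log2 fold change against DMSO (x axis) of the measured members of the 36 tested gene lists (y axis), with tazemetostat in blue and valemetostat in orange. Points are genes, black bars medians, and points beyond -3 or 4 are drawn at the edge. The median of interferon-stimulated genes lies at 0.77 with tazemetostat and 0.82 with valemetostat, and that of activating chromatin factors at -0.26 and -0.33.

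Valemetostat raised the same leading genes. Hdac9 reached 21.9 ± 2.51 CPM (SD, n = 3), a log2 change of 8.66 ± 0.24, Mctp1 rose by 7.63 ± 0.18 and Nab1 by 5.64 ± 0.18. The error for Hdac9 again understates the counting error of its DMSO level. Igf1 rose 369-fold (counting interval 102 to 3050) and Csn3 235-fold (80 to 1140). Dnah12, Sh3tc2, Fam107a, Map2 and Fcer1a rose by 5.39 to 6.77 on the log2 scale. Among the falls, Uevld changed by -1.70 ± 0.21, Col11a2, a collagen chain, by -1.65 ± 0.21, Chd5 by -1.48 ± 0.21 and Lilrb4a by -1.44 ± 0.18. Zc3h12c, an RNA-binding zinc finger protein, went from 68.9 ± 4.88 to 29.7 ± 0.989 CPM. Ndor1, Ankrd16, Anks3, Tsc22d2 and Mid1 changed by -1.33 to -1.11. The largest edgeR quasi-likelihood adjusted p of these 20 genes was 0.000614, for Ndor1. The Chd5 call was lost on log2(TPM + 1) values, with limma-trend adjusted p = 0.893.

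With valemetostat 4927 genes (39.2%) were called, 2577 higher and 2350 lower, and 83.5% of them lay under 2-fold. The majority turned with library totals (2413 higher and 2549 lower) and with the length and GC offset (2384 and 2444). Of 812 genes changed at least 2-fold, 676 were higher (83.3%), and 459 of these were under 1 CPM in DMSO. The libraries did not overlap for 6104 genes (48.5%, against 10% by chance). On log2(TPM + 1) values 3252 genes were called, 36.3% of them higher against 52.3%, and 207 at least 2-fold, and the filter of at least 1 CPM left 530 genes at 2-fold.

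Interferon-stimulated genes also rose with valemetostat. Of 38 members 28 rose, 16 at least 2-fold, and 1 fell (30 called when adjusted over the list alone), with camera adjusted p = 1.95e-10 and adjusted p = 0.0137 with an estimated correlation. Oas1a, a sensor of double-stranded RNA, rose by 4.72 ± 0.28 and Gbp2 by 2.27 ± 0.13 on the log2 scale. In MHC class I presentation 19 of 22 rose and 1 fell (20 when adjusted over the list alone), with adjusted p = 8.52e-08 and adjusted p = 0.129 with an estimated correlation. In MHC class II presentation 10 of 14 rose and 1 fell (11 when adjusted over the list alone), with adjusted p = 7.19e-06 and adjusted p = 0.223 with an estimated correlation. H2-D1 rose by 0.50 ± 0.04 and Ifi30 by 0.67 ± 0.04. Of IL-4 and STAT6 targets 12 of 19 rose and 2 fell (15 when adjusted over the list alone), with adjusted p = 0.00088 and adjusted p = 0.223 with an estimated correlation. In glycolysis 10 of 19 rose and 1 fell (11 when adjusted over the list alone), with adjusted p = 0.00228, adjusted p = 0.25 with an estimated correlation, and 0.126 on log2(TPM + 1) values. Of T cell and NK cell genes 9 of 21 rose and 1 fell (10 when adjusted over the list alone), with adjusted p = 0.00179 and adjusted p = 0.129 with an estimated correlation. Of 10 neuronal genes 5 rose (7 when adjusted over the list alone), among them the synaptic vesicle gene Syp by 1.87 ± 0.29. Camera gave adjusted p = 0.0329, adjusted p = 0.269 with an estimated correlation, and 0.0815 without DMSO 3. With tazemetostat 5 neuronal genes rose (5 over the list alone) and camera gave adjusted p = 0.0706, adjusted p = 0.297 with an estimated correlation, and 0.0341 under the length and GC offset and 0.0443 without tazemetostat 3.

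Some genes of chromatin activation and DNA repair also fell with valemetostat. Of activating chromatin factors 17 of 21 fell (19 when adjusted over the list alone), with Kmt2a at -0.92 ± 0.08, camera adjusted p = 9.74e-08 and adjusted p = 0.287 with an estimated correlation. In homologous recombination 12 of 26 fell and 1 rose (13 when adjusted over the list alone), with Brca2 at -0.74 ± 0.06, adjusted p = 0.00104 and adjusted p = 0.223 with an estimated correlation. In alternative end joining 7 of 12 fell (8 when adjusted over the list alone), with Polq at -0.74 ± 0.08, adjusted p = 0.00433 and adjusted p = 0.129 with an estimated correlation. In checkpoint signalling 8 of 17 fell (9 when adjusted over the list alone), with adjusted p = 0.0189 and adjusted p = 0.297 with an estimated correlation. In class switch machinery 17 of 33 fell and 4 rose (22 when adjusted over the list alone), with adjusted p = 0.0329, adjusted p = 0.223 with an estimated correlation, and 0.0861 on log2(TPM + 1) values. Without valemetostat 3 the checkpoint list was at 0.058 and the class switch list at 0.0779. In cholesterol biosynthesis 13 of 23 fell (16 when adjusted over the list alone). Lss, the lanosterol synthase, changed by -0.37 ± 0.05. Camera gave adjusted p = 7.19e-06, and adjusted p = 0.289 with an estimated correlation. With tazemetostat 5 of these 23 genes fell and 2 rose (6 over the list alone), with adjusted p = 0.0959, adjusted p = 0.694 with an estimated correlation, and adjusted p = 0.027 on log2(TPM + 1) values and 0.0483 with library totals. Of 12 DNA methylation factors 6 fell and 1 rose (7 when adjusted over the list alone), with adjusted p = 0.0421 and adjusted p = 0.424 with an estimated correlation. That call was also lost with the length and GC offset (0.358), on log2(TPM + 1) values (0.215) and without DMSO 1 (0.0913), valemetostat 2 (0.0511) or valemetostat 3 (0.0524). With tazemetostat 1 rose and 5 fell (6 over the list alone, adjusted p = 0.149).

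The inhibitors were compared with each other through their fold changes against DMSO. Over 12580 genes the log2 fold changes correlated at r = 0.939 across genes, which are not independent replicates. Groups simulated around the observed DMSO means gave 0.099 on average in 20 simulations (-0.0112 to 0.211). Drawing around these means leaves out the DMSO error that both real comparisons share. A correlation near 0 was therefore built in and is no baseline for 0.939. The covariance was 0.694, and 0.00503 in the same simulations. The difference of 0.689 is for the same reason no measure of a shared change. The DMSO group cannot be split into parts of at least 2 libraries. The part of the correlation that comes from the shared libraries was therefore not measured. Of the genes called higher 2121 were shared, against 514 for independent lists, and of those called lower 1813, against 427. At 2-fold 601 increases and 60 decreases were shared, against 37.4 and 1.19, and 2 genes were called in opposite directions. Both sets of calls share the DMSO libraries and cannot be independent, so the numbers for independent lists are no baseline. The part of these overlaps that comes from the shared libraries was not measured. For the mean of both inhibitors against DMSO, 5559 genes were called, 2851 higher and 2708 lower, and 875 at least 2-fold, 720 of them higher (82.3%). The majority of all calls turned with library totals (2585 higher and 3038 lower) and with the length and GC offset (2657 and 2856). The 6 inhibitor and 3 DMSO libraries did not overlap for 4687 genes (37.3%, against 2.4% by chance). On log2(TPM + 1) values 34.9% of the calls of the mean were higher, against 51.3%.

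**Figure D4:**
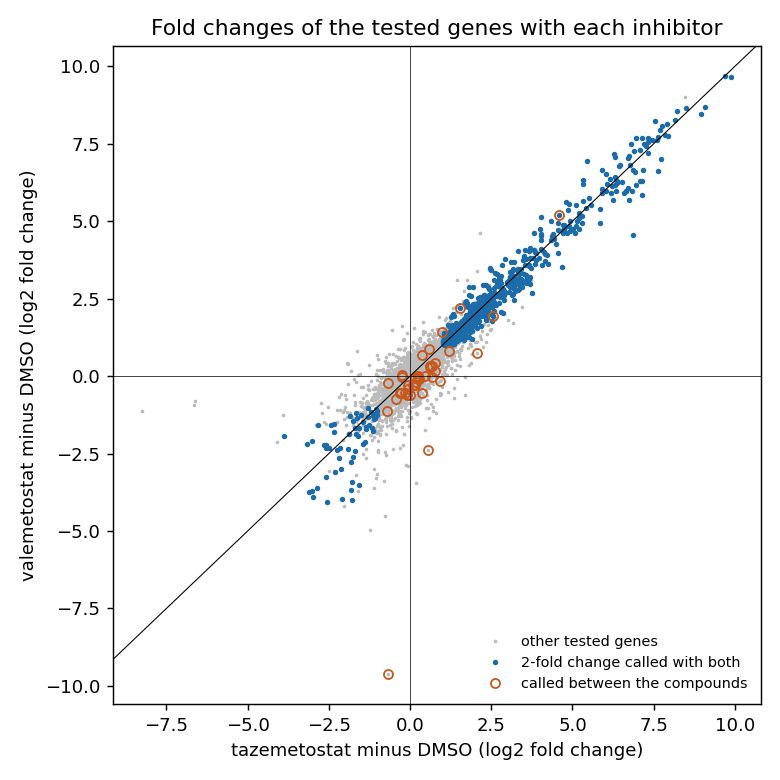
Log2 fold change of each tested gene with valemetostat (y axis) against that with tazemetostat (x axis), both against DMSO, with the line of equal change. Blue points are genes changed at least 2-fold with both, orange circles the 40 genes called between the compounds, and grey points other genes. Points lie along the line, with r = 0.939 across genes.

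Valemetostat and tazemetostat differed in few genes. Both are pyridone amides, tazemetostat with a biphenyl core bearing a morpholine and valemetostat with a benzodioxole core bearing a dimethylaminocyclohexyl group. Their doses are not given in the sources used here and are not known to be matched. Nr4a1, an immediate early nuclear receptor, was at 23.9 ± 4.19 CPM in DMSO, 44.8 ± 5.96 with tazemetostat and 21.4 ± 2.84 with valemetostat (SD, n = 3 each), a log2 difference of -1.07 ± 0.14 between the compounds (edgeR adjusted p = 0.0112). Fos, an AP-1 subunit, differed by -0.59 ± 0.10 and Jun by -0.35 ± 0.06. Rel, an NF-kB subunit, was at 225 ± 16.1 CPM with tazemetostat and 173 ± 6.25 with valemetostat, a difference of -0.38 ± 0.06, and Plau, the urokinase gene, differed by -0.60 ± 0.10. Cyp1a1, a target of the aryl hydrocarbon receptor, was at 1.37 ± 0.332, 5.81 ± 0.541 and 2.32 ± 0.949 CPM in the 3 groups. Higher with valemetostat were Gpr15 (0.66 ± 0.14), Selenop (0.61 ± 0.13), the apolipoprotein gene Apoe (0.42 ± 0.07) and Cldnd1 (0.32 ± 0.05).

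In all 40 genes were called between the compounds, 8 higher and 32 lower with valemetostat. Of 12580 tested genes 999 had an unadjusted p under 0.05, where a share of 0.05 of unchanged genes would lie by chance. Of these 40 genes 4 differed at least 2-fold, Cyp1a1, Nr4a1, Ptp4a1 and Gm14440, the last 2 named after their values were seen. At 2-fold 0 genes remained without tazemetostat 1 or valemetostat 2, and 2 without DMSO 2. The libraries did not overlap for 1773 genes (14.1%, against 10% by chance). For 85.8% of tested genes the 95% interval of the difference lay within 1 on the log2 scale in either direction, and for 75.5% within 0.5. Among the 720 genes raised at least 2-fold by the mean of both inhibitors, 371 (51.5%) had an interval within 1, 340 were further from DMSO with valemetostat and 380 with tazemetostat. Of all 2851 genes higher in the mean of both, valemetostat lay further from DMSO for 53.1%, and of the 2708 lower genes for 57.3%. With the length and GC offset these shares were 48.8% and 52.7%. The count of 40 went to 11 without tazemetostat 1, 19 without tazemetostat 2, 73 without tazemetostat 3, 13 without valemetostat 1 and 9 without valemetostat 2. It was 70 with DESeq2, 81 with the length and GC offset, 93 without a filter and 1 on log2(TPM + 1) values. The calls of Nr4a1, Fos and Plau were lost without valemetostat 1 (edgeR adjusted p = 0.105, 0.0559 and 0.0559). That of Cyp1a1 was lost without tazemetostat 1 (0.103), valemetostat 1 (0.0891) or valemetostat 2 (0.0856), and that of Apoe without tazemetostat 1 (0.0781) or valemetostat 2 (0.0756). Jun was lost without tazemetostat 1 (0.147), valemetostat 1 (0.13) or valemetostat 2 (0.0705). Gpr15 was lost without each inhibitor library but tazemetostat 1 (0.0635 to 0.275), Selenop without each of the 6 (0.0581 to 0.267), and Rel and Cldnd1 without none of the 9.

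Between the compounds 6 lists passed camera at the preset correlation, none of which held with an estimated correlation. In cholesterol biosynthesis 1 of 23 members was called lower with valemetostat (16 when adjusted over the list alone), the median difference was -0.13 and camera gave adjusted p = 1.1e-12, and adjusted p = 0.479 with an estimated correlation. Among immediate early and stress genes Fos, Nr4a1 and Jun of 15 were lower (4 when adjusted over the list alone), with a median of -0.25, adjusted p = 7.34e-06, and adjusted p = 0.479 with an estimated correlation. Among CD40 and NF-kB targets Rel of 35 was lower (2 when adjusted over the list alone), with adjusted p = 7.91e-05, and adjusted p = 0.479 with an estimated correlation. Against DMSO 5 immediate early genes rose and 2 fell with tazemetostat, and 3 rose and 3 fell with valemetostat (7 and 7 over the list alone, 0.0852 and 0.97). Of the CD40 list 14 rose and 3 fell, and 10 rose and 9 fell (20 and 19 over the list alone, 0.061 and 0.697). With tazemetostat the immediate early list passed without DMSO 2 (0.0479) or tazemetostat 3 (0.0432), and the CD40 list without DMSO 2 (0.0364), DMSO 3 (0.0432), tazemetostat 2 (0.0466) or tazemetostat 3 (0.0432), while both had adjusted p = 0.468 with an estimated correlation. Among TGF-β and SMAD targets 1 of 27 was lower, Runx2 (4 when adjusted over the list alone), with adjusted p = 0.00232, and adjusted p = 0.758 with an estimated correlation. That list was at 0.0911 without valemetostat 1, 0.095 without valemetostat 2 and 0.14 on log2(TPM + 1) values, and against DMSO 7 rose and 4 fell, and 4 rose and 6 fell (11 and 10 over the list alone, 0.576 and 0.85). MHC class II presentation was higher with valemetostat, with 0 of 14 members called (0 when adjusted over the list alone), a median of 0.06, adjusted p = 0.0126, and adjusted p = 0.858 with an estimated correlation. Activating chromatin factors were lower, with 0 of 21 called (0 when adjusted over the list alone), a median of -0.05, adjusted p = 0.0214, and adjusted p = 0.858 with an estimated correlation. With the length and GC offset these went to 0.121 and 0.354. The class II list was at 0.349, 0.0955 and 0.134 without tazemetostat 2, valemetostat 2 and valemetostat 3, and the chromatin list at 0.261, 0.481 and 0.384 without tazemetostat 1, tazemetostat 2 and valemetostat 2. The single-gene call of Runx2 was lost without each inhibitor library but tazemetostat 3 (edgeR adjusted p from 0.0902 to 0.304). Proliferation genes did not pass (0.158, and adjusted p = 0.858 with an estimated correlation), except without tazemetostat 1 (0.0355). The interferon list did not pass, with a median difference of -0.04 and adjusted p = 0.832.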

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

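The length and GC offset and the left-out libraries in the list tests were chosen after the data were seen. Each result here comes from the direct comparison of valemetostat with tazemetostat, tested by edgeR for genes and camera for lists. Groups of 3 libraries are too small to test whether a single library is an outlier, so leaving out a library shows only whether a difference rests on it alone.

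Between the compounds 40 genes differed, 8 higher and 32 lower with valemetostat. The 8 and, by the naming rule, 10 of the 32 are given here. Gm14440 and Ptp4a1 differed further and lay outside that rule. Higher with valemetostat on the log2 scale were Gpr15, a chemoattractant receptor, by 0.66, Selenop, a selenium carrier, by 0.61, the gene ENSMUSG00000102976 listed as Zc3h11a by 0.47, Apoe by 0.42, Cldnd1 by 0.32, Ints5 by 0.29, Ptpn22 by 0.29 and Bcar3 by 0.23. Lower with valemetostat were Cyp1a1 (-1.33), Nr4a1 (-1.07), the gene ENSMUSG00000116275 also listed as Zc3h11a (-0.94), the histone gene H2aw (-0.71), the kinase gene Sgk1 (-0.63), Plau (-0.60), Fos (-0.59), Plk2 (-0.51), Tnfaip2 (-0.45) and Rgs1 (-0.41). The pair of genes listed as Zc3h11a moved in opposite directions, at 52.5, 32.9 and 45.5 CPM and at 34.9, 45.3 and 23.7 CPM in DMSO, tazemetostat and valemetostat, and reads of such a pair are hard to assign. Standard errors of these 18 differences ran from 0.05 to 0.24, and the largest edgeR adjusted p was 0.0366. Of these 18 calls only those of Cldnd1 and ENSMUSG00000116275 held without each of the 9 libraries in turn. The edgeR adjusted p without tazemetostat 1 was 0.22 for Selenop, 0.103 for ENSMUSG00000102976, 0.0781 for Apoe, 0.409 for Ints5, 0.107 for Ptpn22, 0.321 for Bcar3, 0.103 for Cyp1a1, 0.203 for H2aw, 0.185 for Sgk1, 0.23 for Plk2 and 0.114 for Rgs1. Without tazemetostat 2 it was 0.143 for Gpr15, 0.168 for Selenop, 0.0582 for Ints5, 0.164 for Ptpn22, 0.168 for Bcar3, 0.104 for Sgk1 and 0.0582 for Plk2. Without tazemetostat 3 it was 0.126 for Gpr15 and 0.0581 for Selenop. Without valemetostat 1 it was 0.211 for Gpr15, 0.0621 for Selenop, 0.132 for Ints5, 0.122 for Ptpn22, 0.211 for Bcar3, 0.0891 for Cyp1a1, 0.105 for Nr4a1, 0.105 for H2aw, 0.211 for Sgk1, 0.0559 for Plau, 0.0559 for Fos and 0.117 for Plk2. Without valemetostat 2 it was 0.275 for Gpr15, 0.267 for Selenop, 0.0756 for Apoe, 0.31 for Ints5, 0.098 for Ptpn22, 0.325 for Bcar3, 0.0856 for Cyp1a1, 0.22 for H2aw, 0.0954 for Sgk1, 0.225 for Plk2, 0.07 for Tnfaip2 and 0.0954 for Rgs1. Without valemetostat 3 it was 0.0635 for Gpr15, 0.148 for Selenop, 0.0747 for ENSMUSG00000102976 and 0.0791 for Ptpn22.

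The 6 lists below differed between the compounds at the preset correlation. The camera adjusted p was 1.1e-12 for cholesterol biosynthesis, 7.34e-06 for immediate early and stress genes, 7.91e-05 for CD40 and NF-kB targets, 0.00232 for TGF-β and SMAD targets, 0.0126 for MHC class II presentation and 0.0214 for activating chromatin factors. In this order they had adjusted p = 0.479, 0.479, 0.479, 0.758, 0.858 and 0.858 with an estimated correlation, so none of these calls held. Of the 10 splits of these 6 libraries, too few for a share under 0.05, the real one gave 6 lists and the highest other 7.

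Of the 50 immediate early and NF-kB genes 4 were called lower with valemetostat than with tazemetostat (Fos, Jun, Nr4a1 and Rel), 38 had an estimated log2 difference below 0, called or not, and the mean difference was -0.172. Their mean against the DMSO mean was 0.223, 0.175 and 0.169 in the tazemetostat libraries and -0.012, -0.034 and 0.091 in the valemetostat libraries. A trend with transcript length and GC content was argued against by the mean of -0.183 with the offset. A single library as the whole source of the mean difference was argued against by means of -0.151 or further from 0 without any 1 of the 6 inhibitor libraries. The lists of these genes are among those called above in this same comparison. Their counts and means are therefore no separate support for a difference. A difference between the compounds, in effective dose or in handling before harvest may each account for the pattern and stay open, since none was tested and doses are not known to be matched.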

How the results depend on the processing

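The length and GC offset and the left-out libraries in list tests were chosen after seeing the data. No called gene or list among those named reversed in direction under any alternative run. Of up to 346 values of named genes per alternative, 66 calls were lost and 1 gained on log2(TPM + 1) values, 6 lost and 1 gained with the offset, 3 lost with library totals, 2 with DESeq2, 1 with the CPM filter, where some genes were not tested, and 1 with only the groups compared. The last 2 were both Iglc2 with valemetostat (adjusted p = 0.0508 and 0.0698). Median-ratio factors and no filter lost 0. Of 3114 values without 1 library, 111 calls were lost. At 34080504 to 46675110 counts per library, 3 counts correspond to at most 0.088 CPM, and folds of genes near this level have wide intervals. The cause of a changed call was not tested unless the construction of the alternative shows it.

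Adding 1 to TPM by construction shrinks the log2 fold changes of genes at low TPM, so fewer of them can reach 2-fold. How much of the lower counts comes from it was not measured. On log2(TPM + 1) values 3100, 3252 and 1 genes were called with tazemetostat, with valemetostat and between them, and 207, 207, 0 and 199 at 2-fold, the last for the mean of both. Between the compounds limma-trend gave 0 at 2-fold beside the 4 of edgeR and 5 of DESeq2. There 999 of 12580 genes had an unadjusted edgeR p under 0.05, where a share of 0.05 of unchanged genes would lie by chance. With the CPM filter, which tests fewer genes, the 2-fold counts were 531, 530, 2 and 533. Between the compounds 70 genes were called with DESeq2, 93 without a filter (12 at 2-fold) and 81 with the offset. Without 1 library this count ran from 9 to 73, and at 2-fold from 0 to 4. The correlation of the inhibitors' fold changes was 0.677 without a filter, 0.894 on log2(TPM + 1) values, and 0.888 to 0.937 without 1 library. The share of genes higher in the mean of both that lay further from DMSO with valemetostat was 57.8% with library totals, 50.2 to 57.0% without 1 library, and 48.8% with the offset, which turns its direction. For genes lower in the mean it was 52.7% with library totals, 52.7% with the offset and 50.7 to 63.0% without 1 library.

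With an estimated correlation, camera adjusted p of lists called at the preset one was, with tazemetostat, 0.275 for class switch machinery, 0.297 for homologous recombination, 0.198 for alternative end joining, 0.359 for checkpoint signalling, 0.165 for MHC class I, 0.297 for MHC class II, 0.297 for IL-4 targets, 0.275 for glycolysis, 0.366 for chromatin factors and 0.135 for T and NK cell genes. With valemetostat these were 0.223, 0.223, 0.129, 0.297, 0.129, 0.223, 0.223, 0.25, 0.287 and 0.129, beside 0.289 for cholesterol biosynthesis, 0.424 for DNA methylation and 0.269 for neuronal genes. Between the compounds they were 0.858 for MHC class II, 0.479 for CD40 targets, 0.758 for TGF-β targets, 0.479 for cholesterol biosynthesis, 0.858 for chromatin factors and 0.479 for immediate early genes.

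Fry, which asks whether the members of a list move one way and not whether they move more than other genes, also called lists that camera did not. With tazemetostat these were PRC2 subunits (adjusted p = 0.000323), HOX genes (0.00811), developmental regulators (0.00811), cyclin-dependent kinase inhibitors (0.0281), mature B cell genes (0.00276), CD40 targets (0.00272), TGF-β targets (0.0422), apoptosis regulators (0.0281), DNA methylation (0.0455), myeloid (0.000307), stromal (0.00149), erythroid (0.00811), early B cell (0.00134), neuronal (0.00167) and immediate early genes (0.00811). With valemetostat they were PRC2 subunits (0.000114), HOX genes (0.0271), developmental regulators (0.0247), cyclin-dependent kinase inhibitors (0.00995), immunoglobulin constant region genes (0.0312), mature B cell genes (0.00164), apoptosis regulators (0.0336), myeloid (0.000245), stromal (0.00164) and early B cell genes (0.000448). Between the compounds fry called none of the 6 lists, with 0.487 for MHC class II, 0.145 for CD40 targets, 0.197 for TGF-β targets, 0.141 for cholesterol biosynthesis, 0.76 for chromatin factors and 0.141 for immediate early genes.

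On log2(TPM + 1) values the list calls lost were class switch machinery (adjusted p = 0.0627 with tazemetostat, 0.0861 with valemetostat), glycolysis (0.126) and DNA methylation (0.215) with valemetostat, and MHC class II (0.14) and TGF-β targets (0.14) between the compounds. Those gained were HOX genes (0.0316), cholesterol biosynthesis (0.027), stromal (0.0316) and neuronal genes (0.0126) with tazemetostat and myeloid genes (0.0152) with valemetostat. With the offset DNA methylation (0.358) was lost with valemetostat, and MHC class II (0.121) and chromatin factors (0.354) between the compounds. Stromal genes were gained with both (0.0337 and 0.0374) and neuronal genes with tazemetostat (0.0341). Without a filter CD40 targets (0.0159) and stromal genes (0.0201) were gained with tazemetostat, and mature B cell (0.0262), myeloid (0.0262) and stromal genes (0.0262) with valemetostat. Library totals added cholesterol biosynthesis (0.0483), stromal (0.0336) and neuronal genes (0.0479) with tazemetostat, and the CPM filter lost class switch machinery (0.0572) with tazemetostat.

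Without 1 library, camera adjusted p ran with tazemetostat from 0.0364 to 0.103 for CD40 targets, 0.0252 to 0.127 for stromal, 0.0443 to 0.139 for neuronal and 0.0432 to 0.149 for immediate early genes. With valemetostat it ran from 0.0169 to 0.0779 for class switch machinery, 0.044 to 0.364 for immunoglobulin constant region genes, 0.00655 to 0.058 for checkpoint signalling, 0.0466 to 0.127 for mature B cell genes, 0.0161 to 0.0913 for DNA methylation, 0.043 to 0.167 for stromal and 0.0234 to 0.0815 for neuronal genes. Between the compounds it ran from 0.000803 to 0.349 for MHC class II, 0.000215 to 0.095 for TGF-β targets, 0.0355 to 0.496 for proliferation genes and 1.15e-05 to 0.481 for chromatin factors.

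With the replicate number as a block 4527, 4713, 32 and 5356 genes were called for tazemetostat, valemetostat, the compounds against each other and the mean of both, and 785, 792, 3 and 867 at 2-fold. Calls of 5 named genes missed the threshold there, Bcar3, Pmaip1, Runx2, Selenop and Piwil2, and no list call changed. The labels do not say that a number marks a shared culture or day. Deviations of libraries with the same number correlated at -0.19 to 0.16, with 1 of 9 pairs over 0.1, and 1 of 9 libraries correlated best with its own number, so no pairing by number was seen. These values do not exclude a weaker effect shared by libraries with the same number.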

Other observations

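The length and GC offset, the test of X-linked genes, the length tests of the chromatin factor list alone, the tests of low counts by DMSO level and the genes named here outside the lists were chosen after their values were seen. In all 6 inhibitor libraries 17 genes with 0 counts in the 3 DMSO libraries reached at least 10 counts. With 0 counts in the 6 inhibitor libraries and at least 10 in each of the 3 DMSO libraries there were 0 genes. The second rule asks for 0 counts in more libraries, so 17 and 0 cannot be compared directly. Among the 17 were Ido1, a tryptophan-degrading enzyme, at 1.73 ± 0.11 CPM with tazemetostat and 1.31 ± 0.49 CPM with valemetostat (SD, n = 3 each), Enpp1 at 1.58 and 1.12 CPM and the neuronal adhesion gene Nrcam at 0.939 and 1.19 CPM. Others were Armcx2, Cobl, Iqgap2, Itih5, Lin28b, Lum, Neurod4, Nxf7, Pde1a, Rapgef5, Rgs21, Shroom3, Slc4a10 and 1 gene without a symbol of a studied gene. The macrophage lysozyme gene Lyz2 rose 52.6-fold (counting interval 17.7 to 257) and 51.4-fold (17.2 to 252), and the complement receptor gene Cr2 72.4-fold (24.5 to 354) and 103-fold (34.8 to 501).

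Counts assigned to nuclear copies of mitochondrial sequence were among the more abundant that fell. Gm13340 was at 3890 CPM in DMSO, 2420 CPM with tazemetostat and 1820 CPM with valemetostat, with log2 changes of -0.68 and -1.10 (edgeR adjusted p = 0.00204 and 0.000146). Gm28661 was at 1400, 853 and 649 CPM and Gm29216 at 1020, 658 and 495 CPM, while Gm28437 was at 2350, 2560 and 2420 CPM. The count table has 0 rows named as mitochondrially encoded (mt-), and reads of such genes and of the nuclear copies are hard to separate. Counts on the copies may therefore include reads of mitochondrial transcripts.

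Calls of at least 2-fold against DMSO were mostly increases, 86.4% with tazemetostat and 83.3% with valemetostat. The choice of TMM over library totals was argued against as a cause. A shift of all genes by at least 0.53 on the log2 scale would be needed to equalise increases and decreases. Library totals moved the median gene by at most 0.026. Both scalings are relative, so a change in RNA per cell would not show in either and stays open. A length and GC trend was argued against by the increases under the offset, 85.4% with tazemetostat and 82.7% with valemetostat. Among genes with a mean of at least 10 CPM over the 9 libraries, increases made up 95.7% of the calls with tazemetostat and 87.5% with valemetostat. This decides nothing on low counts, since 52.3 and 50% of these increases, in the same order, pass only through their rise. Among genes of at least 10 CPM in DMSO, 42 of 47 calls with tazemetostat were increases (89.4%, exact binomial interval 76.9 to 96.5). This argues against low counts as the whole cause for these genes. With valemetostat 42 of 56 were increases (75%, 61.6 to 85.6), with 3 increases and 5 decreases at 100 CPM or more, which leaves low counts open. Both intervals take genes as independent, which they are not, and may be too narrow. Loss of repression by the inhibited methyltransferase may also account for the increases and was not tested, since histone marks were not analysed here.

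Lists with chromatin and repair genes were called lower (10 calls, adjusted p = 0.129 to 0.366 with an estimated correlation) and presentation, interferon and glycolysis lists higher (8 calls, adjusted p = 0.129 to 0.297 with an estimated correlation, apart from interferon-stimulated genes at 0.0113 and 0.0137), in libraries whose fold changes also followed transcript length. With the offset 10 of 10 calls at the preset correlation were kept for chromatin factors, homologous recombination, alternative end joining, checkpoint signalling and class switch machinery, and 8 of 8 for MHC class I and II presentation, interferon-stimulated genes and glycolysis, which argues against the trend as the whole cause for these lists as a set. The set leaves out lists called lower with valemetostat alone. Of these, DNA methylation factors (median transcript 6638 nt) lost the call with the offset (camera adjusted p from 0.0421 to 0.358). Cholesterol biosynthesis kept it (adjusted p = 1.8e-06), so the trend stays open for DNA methylation factors. Summed over the lists of the set, 71% of the lower and 85% of the higher medians was left, the latter mostly from the interferon list (0.77 to 0.76 and 0.82 to 0.80), while MHC class II went from 0.27 to 0.18 and from 0.34 to 0.21 and, with valemetostat, glycolysis from 0.12 to 0.06 and checkpoint signalling from -0.13 to -0.08. The mean of the chromatin factor list followed the length rho of the libraries also within groups (slope 0.405, 95% interval 0.289 to 0.521), and with this rho as a term 25.8% of its difference from DMSO was left with tazemetostat and 18.5% with valemetostat (2.9 to 33.5% without any 1 library), so most of the difference may come from the trend. With the offset 27.3 and 40.7% of the median of this list was left and its calls were kept (adjusted p = 0.00367 and 6e-04), and a technical trend and a lower expression of its members cannot be told apart, because the offset and the rho remove a length-related change of either origin.

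As a hypothesis, the increases may cluster along chromosomes, as silenced domains would. Of 12554 genes placed in the order of GENCODE M21, 598 rose at least 2-fold with both inhibitors, and 74 adjacent pairs had both members increased. Shuffling the increases within 20 bins of expression level 10000 times gave 30.4 pairs on average and 13 to 49 in all (permutation p = 1e-04, one-sided, the smallest these shuffles can give). The bins used the mean over the 9 libraries, which a rise itself lifts. Clustering of genes that are low in DMSO, risen or not, was therefore not separated from clustering of the increases. Paralogs and overlapping genes next to each other could add such pairs, and this was not separated. Of X-linked genes 27 of 358 (7.54%) rose, against 571 of 12196 autosomal genes (4.68%), with an odds ratio of 1.66 (95% interval 1.07 to 2.49, Fisher's exact p = 0.0165, two-sided, without adjustment). Fisher's test takes genes as independent, which neighbouring increases may not be, so this interval and p may be too small. It also took no account of expression level.

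Other assignments of the libraries were also tested. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In each of the following 1 of 10 splits, the real one, gave as large a result. With tazemetostat the real split gave 4794 genes and the highest other 0, at 2-fold 806 and 0, and 11 and 9 lists. With valemetostat the values were 4927 and 0, 812 and 0, and 14 and 12 lists. Between the compounds they were 40 and 1 genes and 4 and 1 at 2-fold, while 2 of 10 splits gave at least as many lists, 6 in the real split and 7 in the highest other. For 6 inhibitor against 3 DMSO libraries as 2 groups, 1 of 84 splits, the real one, gave as many genes. It gave 5429 against 1 in the highest other, and 876 against 1 at 2-fold. The other splits mix inhibitor and DMSO libraries, which widens their spread. This argues against chance assignment at 0.05 only if the 9 libraries are independent units. The labels do not say that they came from separate cultures, so a difference between cultures or in handling is not excluded.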
